A study of Rattus norvegicus with 4 samples.

How the data were processed

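Per the labels' protocols, livers were frozen 18 h after injection of ANIT (75 mg/kg, dissolved in olive oil at 7.5 mg/mL) or of olive oil, total RNA of 3 rats per treatment was mixed, and poly(A) RNA was purified. It was labelled by reverse transcription with Cy3 and Cy5 nucleotides and hybridised to a glass cDNA array of 1800 rat genes. Housekeeping genes and lambda DNA were also spotted. ANIT was in Cy5 on 2 arrays and in Cy3 on the other 2, so that the 4 arrays form a technical dye swap of one pair of pools and count as 1 replicate of the treatment.

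The deposited values are log ratios of both channels, taken here as log2. Background correction, normalization, log base, centring and direction are not given in the sources used here. The deposited log2 columns had medians of -0.53, 0.85, -0.53 and 0.83 and were therefore not centred on the median. The table had 0 missing values and all 4 columns were used. Spot intensities were not analysed here, so neither dim spots nor an intensity-dependent dye difference could be removed.

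Of 1936 probes, 1432 had 1 gene symbol in the platform annotation, 19 had several and were not named, and 485 were not listed there and are unnamed here. Symbols were updated through Entrez identifiers to a RefSeq gene table of the rat assembly GRCr8, which matched 1429 of the 1432 probes; the other 3 kept their symbol. The annotation names no genome build, so no coordinates are given. Of the 958 genes, 340 had more than 1 probe, with at most 8.

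Each array was centred on its median over all probes, probes of a gene were averaged, arrays were averaged within each dye orientation and then over both. A gene was counted where its mean ratio was at least 2-fold and every array had the sign of the mean. Before the data were examined, the groups, this rule, 28 gene lists, the alternatives and the choice of named genes were fixed. Named genes were the 12 highest and the 12 lowest counted genes (or all, where fewer were counted), up to 4 members of each list with at least 5 measured genes by size of the ratio, and the spotted housekeeping genes. Me1, Dgat1, A2m, Abcc4, Myc, Mgst1, Calr and Pdia3, further list members, were added after their values were seen. List medians were ranked among 10000 random lists drawn from the measured genes, as a description without a test. Serpina3k and Mt1a were measured under the updated symbols Serpina3c and Mt1.

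The rule fixed beforehand said that a negative correlation between arrays of opposite dye marks a dye ratio, to be turned on the arrays with ANIT in Cy3. The correlation was negative, but the largest values kept their sign on all 4 arrays. After the data were seen, the table was therefore read as already turned to one treatment ratio. The fixed rule as written, with arrays centred on their medians after turning, was run as an alternative, and it leaves 0 genes at 2-fold.

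Gene ratios were also fitted with limma 3.58.1 in R 4.3.3, with dye orientation as a term and the intercept tested against 0, with Benjamini-Hochberg adjustment. This fit has hybridisation error and no error between animals. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Both rules were tested on simulated data for this comparison of 958 genes, 200 of them changed. At a simulated log2 size of 1.5, the size rule and limma each found 100% of 100 genes. At 0.8, the size rule found 0% and limma 100% of 100 genes. Among 758 unchanged genes, the size rule counted 0% and limma called 0.528%. Every simulated gene had the median SD within dye orientation (0.068), whereas the 95th percentile of the real genes was 0.182. The simulated dye difference was also symmetric about the true ratio. These shares are therefore a best case, and the 0% at 0.8 was set by the cut at a log2 size of 1.

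The alternatives were no centring, centring on Hprt1 and Actb (Gapdh was not among the named probes), the median over arrays, stricter or looser needs for values, the probe of each gene with the smallest SD over all 4 arrays, each dye orientation alone, each array left out in turn, the sign turned, other sizes (1.5-fold and 3-fold), the sign rule on orientation means, and limma with a robust prior, without the dye term, or at 0.01. Besides the change of the main reading, added after the data were seen were natural logs, the probe of each gene with the smallest SD within dye orientation, random lists and pairs of lists matched on the difference between dye orientations, and the ribosomal list without S6 kinases.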

Results

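Liver RNA of male Sprague-Dawley rats was compared 18 h after a single intraperitoneal dose of alpha-naphthylisothiocyanate (ANIT, 75 mg/kg) or of its vehicle, olive oil. ANIT is a liver toxicant used in rats to injure bile duct cells and stop bile flow. Total RNA of 3 rats per treatment was mixed, and the pair of pools was hybridised to 4 spotted cDNA arrays, with ANIT in Cy5 on arrays 1 and 3 and in Cy3 on arrays 2 and 4. The table held 1936 probes without missing values, of which 1432 were assigned to 958 genes. Because every array carried the same pair of pools, the treatment had 1 replicate and no test of it was possible. The errors below are the SD between arrays of one dye orientation, pooled over both orientations (n = 4 arrays), and describe hybridisation alone. The number of arrays limits the precision, and spot brightness was not analysed here.

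The question addressed was which liver transcripts differed 18 h after ANIT. On the log2 scale, 12 genes were at least 2-fold higher and 11 at least 2-fold lower in the ANIT pool, with the same sign on all 4 centred arrays. The remaining 935 genes were not counted, and 875 (91.3%) had mean ratios between -0.5 and 0.5. Cyp1a2, a cytochrome P450 of drug metabolism, was highest at 2.0 ± 0.025 (4.01-fold), and the lipid desaturase gene Scd was lowest at -3.19 ± 0.25 (9.13-fold lower). The direction, ANIT over olive oil, is the likely one, since the sample titles name ANIT and it is listed as the second channel. The table states neither its direction nor its log base, which was taken as 2.

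Among the higher genes, Mt1, a metal-binding metallothionein, had a log2 ratio of 1.80 ± 0.083 (3.49-fold), and Sqstm1, an adaptor protein of selective autophagy, had 1.71 ± 0.026 (3.28-fold). Alpl, the alkaline phosphatase of liver and bone, followed at 1.5 ± 0.15 (2.84-fold), with close values from both of its probes (1.37 and 1.64). The plasma acute phase protein genes Orm1 and Lbp stood at 1.48 ± 0.072 and 1.29 ± 0.025. Creld2, an endoplasmic reticulum stress gene, stood at 1.45 ± 0.19. Nr0b2, the nuclear receptor SHP that represses bile acid synthesis, was 2.57-fold higher (1.36 ± 0.098), and Stat3, a transcription factor of cytokine signalling, was 2.38-fold higher (1.25 ± 0.059). Ifrd1 (1.24 ± 0.12), the lipoxygenase gene Alox15 (1.06 ± 0.071) and Por, the reductase that passes electrons to cytochromes P450 (1.05 ± 0.081), completed the higher genes, and the latter pair lay under 2-fold when arrays were centred on Hprt1 and Actb. Por rested on 5 probes that disagreed, 3 of them between 1.55 and 1.85 and the others at 0.055 and 0.088.

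Among the lower genes, Car3, a carbonic anhydrase abundant in male rat liver, followed Scd at -2.74 ± 0.016 (6.67-fold lower). The growth factor receptor gene Fgfr3 (-1.67 ± 0.16), Tsc22d1 (-1.64 ± 0.11) and the vasopressin receptor gene Avpr1a (-1.52 ± 0.31) were about 3-fold lower. Fads2, which encodes a further fatty acid desaturase, had -1.48 ± 0.30 (2.80-fold lower). Pklr, the liver pyruvate kinase (-1.08 ± 0.16), F2r, a thrombin receptor (-1.06 ± 0.14), and Acsl1, which activates long-chain fatty acids (-1.06 ± 0.049), lay near the 2-fold limit. As deposited all of these lay under it (-0.93, -0.91 and -0.91), as did F2r without array 2 (-0.996) and Acsl1 with a single probe (-0.97). The carbonic anhydrase genes Car1 and Car2 had -1.35 ± 0.082 and -1.14 ± 0.084. The probes of Car2 disagreed, with 1 at -2.40 and the other at 0.11, and whether probes of these related genes tell their transcripts apart was not tested.

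**Figure D1:**
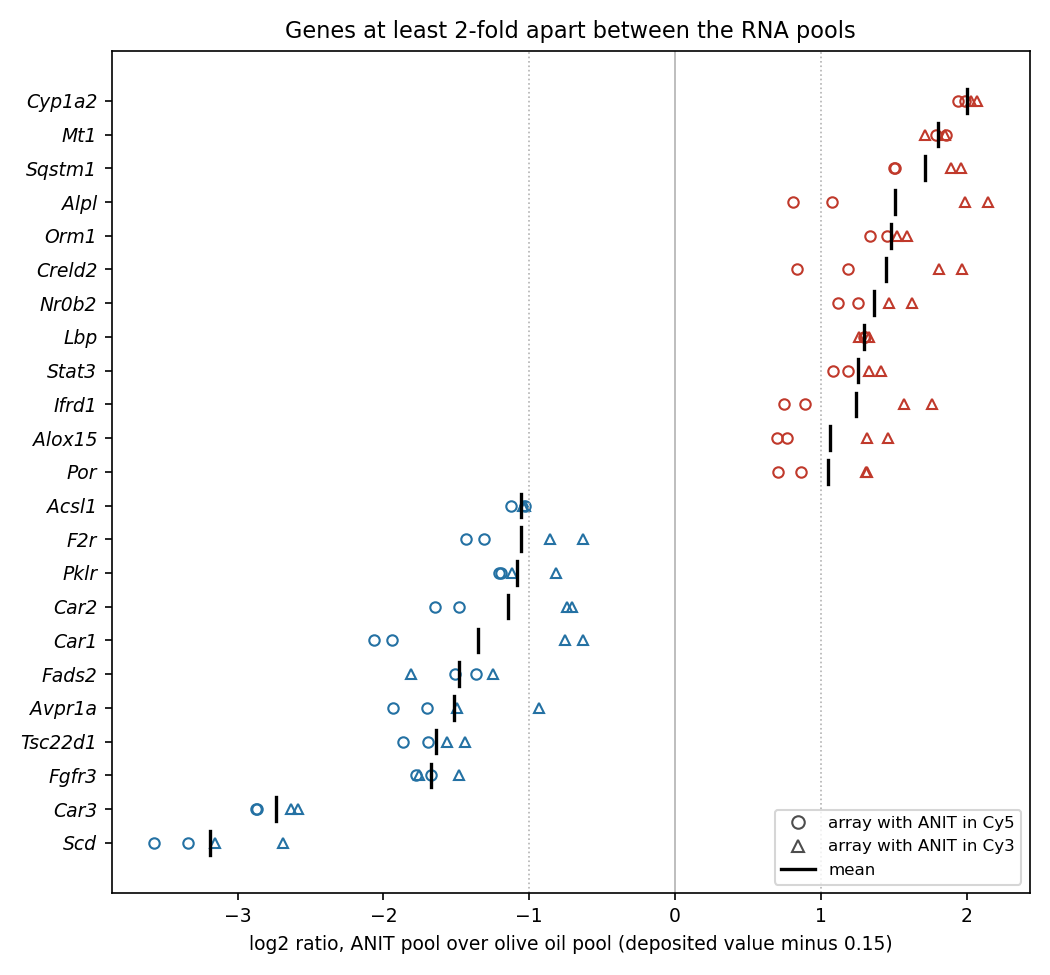
Log2 ratio of the ANIT pool over the olive oil pool for the 23 genes at least 2-fold apart, as deposited less the mean array median of 0.15, on each of the 4 arrays (circles, ANIT in Cy5; triangles, ANIT in Cy3) with their mean (black bar); dotted lines mark 2-fold. All 4 arrays lay on one side of 0 for each gene, from Scd at -3.19 to Cyp1a2 at 2.0.

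Genes of fatty acid synthesis had the lowest median of the 21 lists with at least 5 measured members. Of 7 measured, 3 were counted as lower (Scd, Fads2 and Pklr) and 0 as higher, while Fasn, the fatty acid synthase, had -0.40, Me1 -0.25 and Dgat1 0.01. The list's median of -0.40 stood at the 0.04 percentile of 10000 random lists of the same size. Of 6 genes of fatty acid oxidation, Acsl1 alone was counted. Hadhb, a subunit of the mitochondrial trifunctional protein, had 0.19 over probes at -0.17 and 0.54. The list median of -0.048 stood at the 43.8 percentile.

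Of 10 acute phase genes, Orm1 and Lbp were counted as higher, and the other 8 were not counted. Among the latter, the fibrinogen chain gene Fgg had 0.79, the ceruloplasmin gene Cp 0.38 (0.24 from its probe with the smallest SD within dye orientation), and A2m -0.10. The list's median was 0.28, at the 99.97 percentile of random lists, or 97.7 against lists matched on the difference between dye orientations. Of the negative acute phase list, 7 genes that besides plasma protein genes held Car3, which encodes an enzyme inside the cell, Car3 alone was counted, as lower. Apoa1, the main protein of high-density lipoprotein, had -0.68, Igfals -0.56 and the transthyretin gene Ttr -0.20, and the list median of -0.20 stood at the 0.775 percentile. Car3 and Igfals also belonged to the list of 10 growth hormone and male liver genes, where Car3 was again the member counted. Igf1 had -0.46 in that list, and its median was -0.13 (4.16 percentile).

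Among 9 genes of bile acid synthesis and transport, Nr0b2 was counted as higher and 0 as lower, whereas the list median was -0.23 (0.075 percentile). Nr1h4, which encodes the bile acid receptor FXR, had -0.68, the bile acid uptake transporter gene Slc10a1 -0.51, and Cyp7a1, the rate-limiting enzyme of bile acid synthesis, -0.49. Abcc4, an efflux transporter gene, had 0.21. Of 27 genes of the cytochrome P450 system, Cyp1a2 and Por were counted as higher and 25 were not counted. Their median was -0.090 (7.22 percentile) while their mean was 0.0064. Cyp4f1 had -0.60 and the cytochrome b5 gene Cyb5a 0.59. From single probes, Cyb5a had 0.12 on the smallest SD over all 4 arrays and 0.73 on the smallest SD within dye orientation. Of 22 genes of oxidative stress and conjugation, Mt1 alone was counted. Aldh1a1 had 0.90, Gsta2 0.69 and the quinone reductase gene Nqo1 0.66, against -0.64 for Mgst1, and the median was 0.10 (99.5 percentile, or 82.8 against random lists matched on the difference between dye orientations), or 0.045 without array 3.

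Of 17 immediate early and stress genes, Sqstm1 and Stat3 were counted as higher and 15 were not counted. The kinase gene Pim3 had 0.84, the transcription factor gene Egr1 0.71 and Myc 0.49, and the median of 0.24 stood at the 99.99 percentile. None of 11 chaperone genes was counted, with Cct5 at 0.41, Pdia4 at 0.38 and Hspa9 at 0.32 (-0.070 with a single probe), and a median of 0.20 (99.7 percentile). The endoplasmic reticulum chaperone genes Calr and Pdia3 had -0.018 and 0.0065. None of 5 proteasome genes was counted either. Psmd3 had 0.48 and Psmd2 0.40, and the median was 0.30 (98.9 percentile, or 94.96 against random lists matched on the difference between dye orientations). The 14 genes with ribosomal protein symbols had a median of 0.11 (98.2 percentile). The 11 left without the ribosomal S6 kinases had 0.11 (96.8 percentile, or 91.35 when matched in the same way). The median was 0.090 over 7 translation factor genes (91.3 percentile), or -0.038 with a single probe per gene. It was 0.053 over 8 cytoskeletal genes (86.7 percentile), and turned below 0 when arrays were centred on Hprt1 and Actb. Actb is itself a member of the cytoskeletal list, so that setting is no independent check of it. Over 9 genes of amino acid and glucose metabolism the median was -0.083 (24.1 percentile). Gckr, the regulator of glucokinase, had -0.90 there and the glycogen synthase gene Gys2 0.76. Over 8 lipoprotein genes it was -0.067 (32.1 percentile), and over 13 proliferation genes -0.11 (7.42 percentile), with Npm1 at 0.51 and Cdk1 at -0.22 (-0.097 from its probe with the smallest SD within dye orientation). With the probe of smallest SD over all 4 arrays for each gene, medians were 0.46 for acute phase, 0.17 for proteasome and -0.22 for growth hormone genes, and 0.054 for cholangiocyte genes.

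In the 4 lists of other cell types with at least 5 measured genes, no gene was counted, against 23 of all 958 genes. The median was -0.037 over 11 neutrophil and inflammation genes (52.5 percentile), with Icam1 at 0.33, and -0.0077 over 7 cholangiocyte genes (65.8 percentile), with Clu at 0.34. It was -0.068 over 15 stellate cell and fibroblast genes (27.1 percentile), with Col1a1 at -0.58 (-0.38 with a single probe) against Mmp14 at 0.44 and Fn1 at 0.38, and -0.038 over 7 endothelial genes (52.0 percentile), with Kdr at -0.25. The median difference between dye orientations was -2.06 for cholangiocyte, -1.93 for neutrophil, -1.47 for endothelial and -1.32 for stellate cell genes. Of the 484 probes with the most negative differences 0 passed 2-fold, and of the next 484 only 3 higher and 1 lower. The absence of counted genes therefore says little about these cells. Macrophage, lymphocyte and red cell lists had 4, 3 and 1 measured genes and were not ranked. Car1, counted as lower (-1.35), was the red cell gene. Lists of cholesterol synthesis, oxidative phosphorylation, coagulation and complement, and spotted controls held 4, 3, 3 and 2 measured genes. The spotted housekeeping genes Hprt1 and Actb had 0.086 and 0.040, and no probe was named Gapdh.

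**Figure D2:**
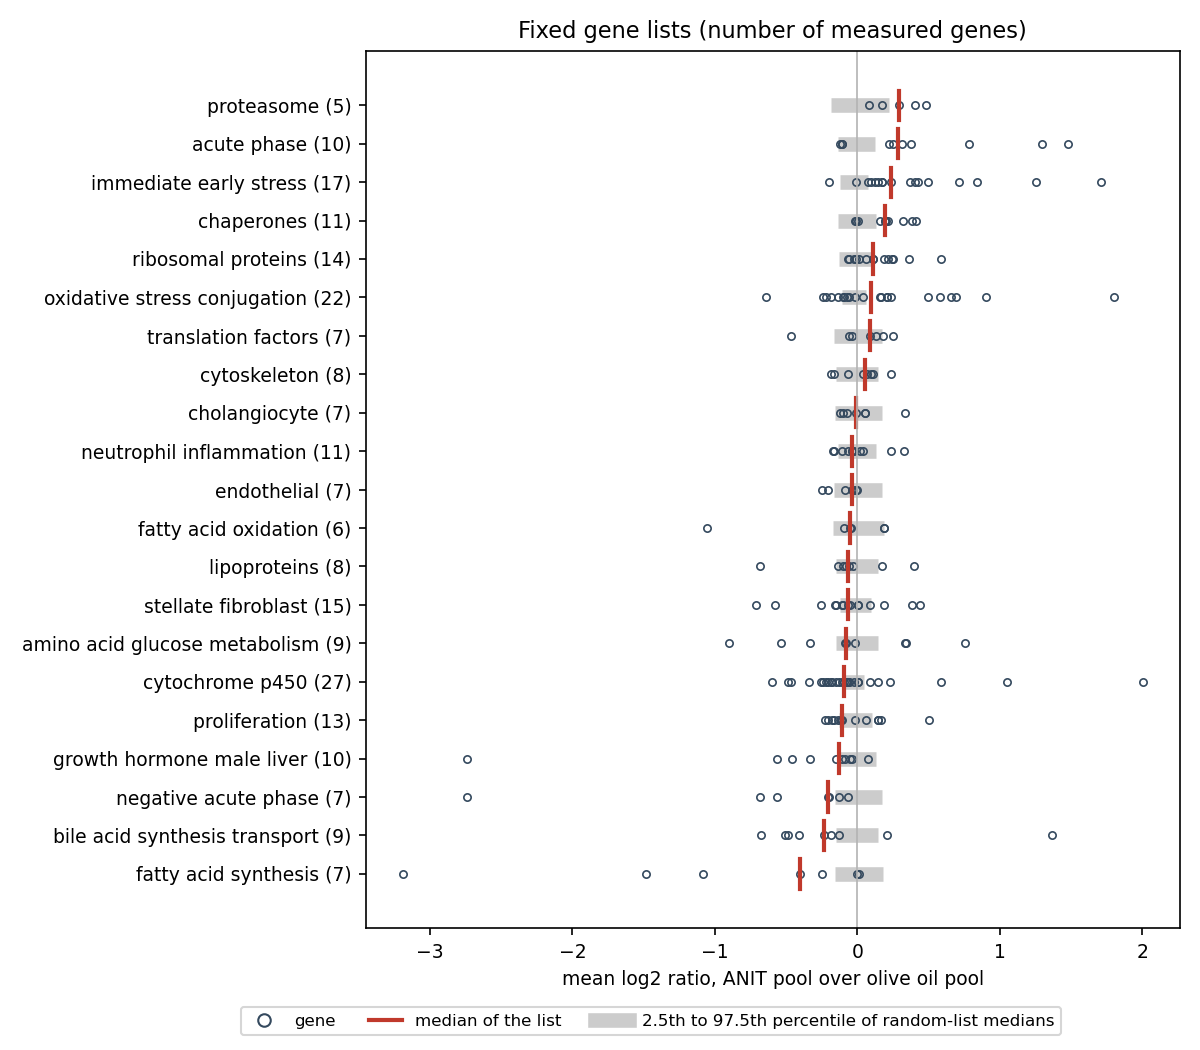
Mean log2 ratio of the ANIT pool over the olive oil pool for the genes (circles) of the 21 fixed lists with at least 5 measured members, the number of which follows each name. Red bars are list medians and grey bars the central 95% of 10000 medians of random lists of the same size; medians ran from -0.40 for fatty acid synthesis to 0.30 for the proteasome.

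With limma, 521 of 958 genes differed between these RNA pools beyond hybridisation error (Benjamini-Hochberg adjusted p under 0.05), 241 higher and 280 lower. This is a statement about the pools and not about the treatment. All 23 genes named above as 2-fold apart were among them. Calls of small ratios depend on where 0 is set, since 322 of the 521 were also called on the values as deposited. After centring, the 484 probes with the most negative difference between dye orientations had a median of -0.12 and an SD of 0.061. A shared offset from 0 of this size can therefore be called as lower, and the list counts below hold for this centring. Of the acute phase list, 7 genes were higher and 2 lower by limma. The counts were 2 higher and 7 lower for bile acid genes, 0 and 5 for fatty acid synthesis, 14 and 1 for immediate early and stress genes, 8 and 0 for chaperones, and 5 and 13 for the P450 system. These counts were the same when adjusted over the list alone. The oxidative stress list gave 10 higher and 4 lower over all genes, and 10 and 5 adjusted over the list alone. Over all genes, limma called 0 higher and 6 lower for both the negative acute phase and the growth hormone lists, 4 and 0 for the proteasome, 8 and 0 for ribosomal genes, 2 and 1 for fatty acid oxidation and 4 and 7 for proliferation. It called 2 and 3 for lipoproteins, 3 and 2 for the cytoskeleton, 2 and 2 for neutrophil and inflammation genes, 3 and 6 for stellate cell genes and 0 and 2 for endothelial genes, all of them unaltered when adjusted over the list alone. Adjusted over the list alone, translation factors went from 3 and 1 to 4 and 1, amino acid and glucose genes from 3 and 3 to 3 and 4, and cholangiocyte genes from 1 and 2 to 1 and 0.

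Centring lowered every mean ratio by 0.15. As deposited, 17 genes were higher and 7 lower, with Car2, Pklr, F2r and Acsl1 under 2-fold, limma called 475 higher and 81 lower, and 10 list medians between -0.13 and -0.0077 lay above 0. Read as a dye ratio, which was the rule fixed before the data were examined, the table gave 0 genes at least 2-fold higher and 0 lower. For this the sign was turned on the arrays with ANIT in Cy3 and each array was then centred on its median.

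A further comparison asked how far the arrays agreed. Scd and Car3 lay far below 0 and Cyp1a2 and Mt1 far above it on every array as deposited, but most probes changed side with the dye. Across probes, which are not independent replicates, Pearson's r was 0.958 to 0.979 between arrays of one dye orientation and -0.383 to -0.370 between opposite orientations, with Spearman's rho of 0.953 to 0.977 and -0.609 to -0.600. Array medians were -0.53, 0.85, -0.53 and 0.83 for arrays 1 to 4. The difference between orientations, Cy5 less Cy3, ran over the probes from -3.30 to 0.36 with a median of -1.25. It was -0.085 for Cyp1a2 and -0.54 for Scd, against -2.06 for the median cholangiocyte gene. Among the 484 probes with the most negative differences, 0 passed 2-fold and the SD of the mean ratios was 0.061, while among the 484 at the other end, from -0.27 upward, 12 were higher and 10 lower with an SD of 0.46. The median over genes of the SD was 0.068 within a dye orientation and 0.44 over all 4 arrays.

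**Figure D3:**
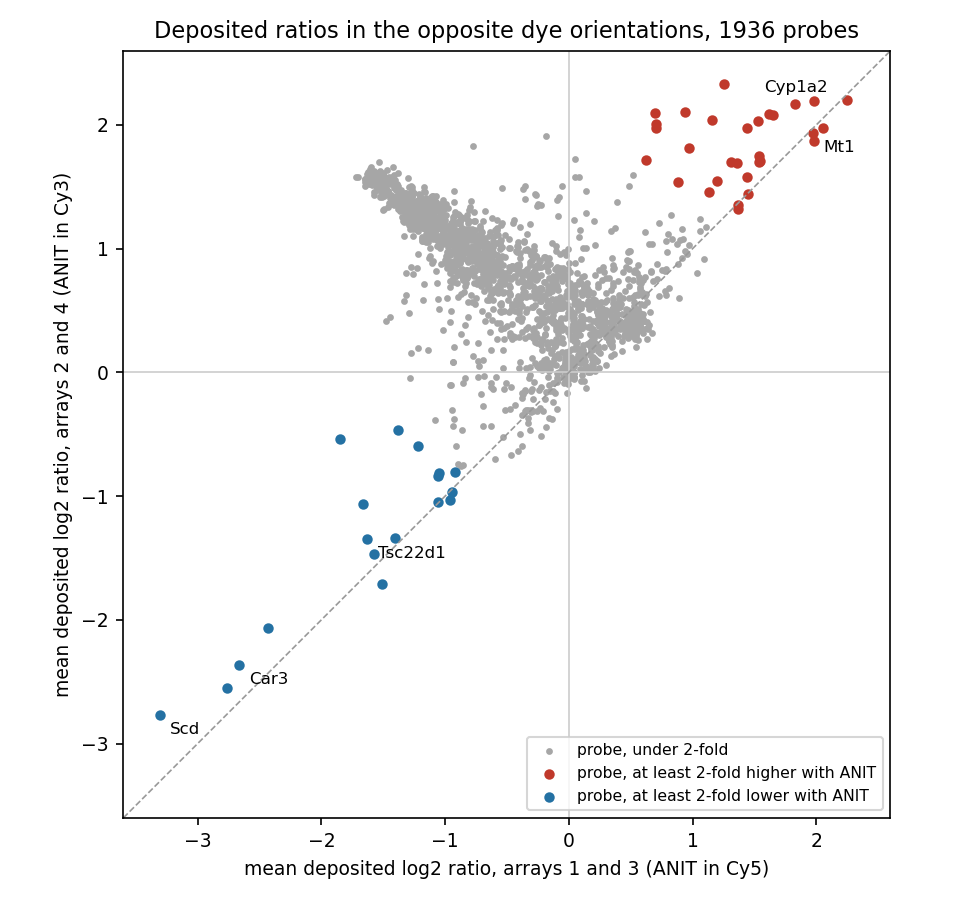
Mean deposited log2 ratio of each of 1936 probes on the arrays with ANIT in Cy5 (horizontal) and in Cy3 (vertical); the dashed line marks equality. The 30 red and 18 blue probes, at least 2-fold higher or lower with ANIT after centring, lie toward the line's ends, while most grey probes lie at the upper left.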

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

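Pck1, which encodes a rate-limiting enzyme of gluconeogenesis, had 1 array far from the others. Its centred log2 ratio was 0.80 on array 3 (0.799) against 0.25, 0.17 and 0.16 on arrays 1, 2 and 4. It was the 1 gene of 93 named genes with such a gap, where chance alone marks about 1 in 20 sets of 4 like arrays. That rate does not carry over here, since the arrays form dye pairs, with a median SD of 0.068 within an orientation against 0.44 over all 4. Such a gap can also miss arrays that disagree within a dye pair. The SD within dye orientation was 0.28 for Pck1 but larger for some other named genes, such as Got1 (0.43) and Ngfr (0.99). Ngfr, of the stellate cell list, had 0.31 on array 2 and -1.66 on array 4.

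Among the probes without a single gene name, which enter no gene value, 10 were at least 2-fold higher in the ANIT pool and 0 were at least 2-fold lower. Of these, 2 had several entries in the annotation and 8 had none, and their mean log2 ratios ran from 1.02 to 1.86.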

How the results depend on the processing

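The main reading of the table, as already turned to one treatment ratio, was chosen after the data were seen, and the dye ratio is the rule fixed before. Natural logs, the matched random lists and pairs of lists, the ribosomal list without S6 kinases and the probe chosen on its SD within dye orientation were also chosen after, and the other settings before. With each array left out in turn, 12 to 13 genes were higher and 11 lower, and limma called 419 to 497. Without array 2, F2r fell just under 2-fold (-0.996). The median over arrays, the sign rule on orientation means and the added limma threshold left all 23 counted genes in place, and the needs for values moved nothing, because no value was missing. Centring on Hprt1 and Actb gave 10 higher and 11 lower genes, with Alox15 and Por under 2-fold, and taking the probe with the smallest SD over all 4 arrays gave 13 and 10, without Por, Car2 and Acsl1. In that setting Car2 turned to 0.11, its other probe. After centring, the SD over all 4 arrays is small for probes whose dye difference is near the median. On the SD within dye orientation, Car2 had -2.40, 11 genes were higher and 12 lower, without Por and Acsl1, the immediate early and stress median was 0.37 and that of fatty acid oxidation turned to 0.023 (-0.081 on the SD over all 4 arrays). Within dye orientation, other medians that moved by over 1.5 times or turned were -0.31 for growth hormone, -0.15 for P450, 0.19 for oxidative stress, -0.11 for stellate cell, -0.044 for amino acid and glucose, 0.17 for proteasome, -0.038 for translation factor and 0.054 for cholangiocyte genes. Cp then had 0.24, Cdk1 -0.097, Col1a1 -0.38, Hspa9 -0.070 and Hprt1 0.034. Medians near 0 of neutrophil, cholangiocyte, endothelial and amino acid and glucose genes moved by over 1.5 times, without a change of sign, when single arrays were left out, and that of oxidative stress genes was 0.045 without array 3. Spot brightness was not analysed, so how far dim signal limits each ratio is unknown.

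As deposited, 17 genes were higher and 7 lower, and the medians were 0.39 for immediate early and stress, 0.24 for translation factor, 0.085 for stellate cell and 0.11 for endothelial genes. The cause is the shift of 0.15. Centred on Hprt1 and Actb, the immediate early and stress median was 0.17. The arrays with ANIT in Cy5 alone gave 59 higher and 7 lower genes, and medians of 0.53 for oxidative stress, 0.18 for fatty acid oxidation, 0.35 for immediate early and stress and 0.32 for ribosomal genes. Those with ANIT in Cy3 alone gave 6 higher and 36 lower genes, and medians of -0.84 for negative acute phase, -0.89 for bile acid, -0.98 for fatty acid synthesis, -0.32 for cytoskeletal and -0.21 for stellate cell genes. The medians of other lists also varied between arrays, with SDs over the 4 arrays of 0.63 for acute phase, 0.49 for proteasome and 0.40 for chaperone genes. Centring sets the median probe to 0 in each orientation. Every gene is thereby shifted up with ANIT in Cy5 (array medians of -0.53) and down with ANIT in Cy3 (array medians of 0.85 and 0.83). Genes whose deposited orientations lay closer together than these medians then have higher ratios with ANIT in Cy5. Cyp1a2, with a deposited difference of -0.085, had 2.65 in the former and 1.36 in the latter. The counts and medians of a single orientation hold this shift by construction. A limit of 1.5-fold gave 34 higher and 21 lower genes, 3-fold gave 3 and 4, and natural logs gave 27 and 16. Without the dye term limma called 5 genes, and at 0.01 it called 336, against 521.

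With the sign of all ratios turned, 11 genes were higher and 12 lower, by construction. The ratios were then -2.0 for Cyp1a2, -1.80 for Mt1, -1.71 for Sqstm1, -1.5 for Alpl, -1.48 for Orm1, -1.45 for Creld2, -1.36 for Nr0b2, -1.29 for Lbp, -1.25 for Stat3, -1.24 for Ifrd1, -1.06 for Alox15 and -1.05 for Por. The lower genes then had 3.19 (Scd), 2.74 (Car3), 1.67 (Fgfr3), 1.64 (Tsc22d1), 1.52 (Avpr1a), 1.48 (Fads2), 1.35 (Car1), 1.14 (Car2), 1.08 (Pklr), 1.06 (F2r) and 1.06 (Acsl1). The medians were 0.40 for fatty acid synthesis, -0.24 for immediate early and stress, -0.11 for ribosomal, -0.090 for translation factor, -0.30 for proteasome and 0.068 for stellate cell genes.

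Read as a dye ratio and centred on array medians, the table gave 0 higher and 0 lower genes. These counts depend on the centring. As deposited, 569 probes had a difference between orientations under -2, and they would pass 2-fold lower by size without it. After centring, the genes counted as lower in the main reading had ratios above 0. They were 0.41 for Scd, 0.55 for Car3, 0.63 for Fgfr3, 0.54 for Tsc22d1, 0.38 for Avpr1a, 0.73 for Fads2, 0.027 for Car1, 0.26 for Car2, 0.57 for Pklr, 0.37 for F2r and 0.66 for Acsl1. Medians were 0.58 for negative acute phase, 0.45 for P450, 0.48 for bile acid, 0.57 for fatty acid synthesis, 0.17 for fatty acid oxidation, 0.17 for immediate early and stress, 0.025 for stellate cell, 0.53 for lipoprotein and 0.36 for growth hormone genes. Here the difference between orientations takes the place of the mean, by construction. Matched on that difference, the percentile moved from 99.5 to 82.8 for oxidative stress genes, from 98.92 to 94.96 for the proteasome, from 96.8 to 91.4 for ribosomal genes without S6 kinases, from 7.22 to 1.22 for the P450 system and from 99.97 to 97.7 for acute phase genes. It moved from 65.8 to 92.9 for cholangiocyte, from 52.5 to 78.1 for neutrophil and inflammation, from 24.1 to 7.05 for amino acid and glucose, from 43.8 to 26.1 for fatty acid oxidation and from 32.1 to 18.7 for lipoprotein genes. For negative acute phase genes it moved from 0.775 to 2.19, and for bile acid genes from 0.075 to 0.695.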

Other observations

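Of the tests in this part, only the comparison of plasma protein and ribosomal genes with markers of other cell types was set out before its result was seen. Even there, leaving the S6 kinases out of the ribosomal genes was chosen after the data were seen. The other tests, and the genes named in the next paragraph, were chosen after.

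Between 1.5-fold and 2-fold, 22 genes were higher and 10 lower with the same sign on all 4 centred arrays, and 13 and 8 of these belonged to no fixed list. The sign rule left out further genes on both sides. At 1.5-fold or more, limma called 39 higher and 25 lower genes, against 34 and 21 with that rule. Some lower genes left out kept their sign on all 4 arrays as deposited. The nucleoside transporter genes Slc28a2 and Slc29a1 had log2 ratios of -0.83 ± 0.057 and -0.64 ± 0.076 (SD within dye orientation, n = 4 arrays). The Wnt coreceptor gene Lrp5 had -0.81 ± 0.061 and Rab25, a small GTPase of vesicle recycling, -0.82 ± 0.047. On the higher side, Sytl1 stood at 0.99 ± 0.034, Cavin3, a caveolar coat protein, at 0.95 ± 0.061, and the stress kinase p38 gene Mapk14 at 0.81 ± 0.12. The cytochrome P450 genes Cyp2b21 (0.85 ± 0.24) and Cyp2u1 (0.77 ± 0.097) were also higher.

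Of 340 genes with several probes, 10 (2.94%) had probes at least 1 apart on the log2 scale, and the median range was 0.14. Of 16 genes with several probes and at least 1 of them past 2-fold, 9 had another probe under 1.5-fold, and 7 of these were not counted as genes. The amino acid transporter genes Slc38a2 (0.41 over 5 probes, the highest at 1.63) and Slc38a3 (0.55 over 5 probes, the highest at 1.47) were among the 7. In another set of values, 48 unnamed spots, 3 in each of 16 equal runs of probe numbers, had deposited values of at most 0.163 in size on any of the 4 arrays. The means of the 3 spots per run had SDs that were 0.0747 to 0.227 times those expected from the spread of single spots, depending on the array. The deposited 0 thus lies at these spots, and the values as deposited are those that gave 17 higher and 7 lower genes. The main counts of 12 and 11 come from centring on array medians, which moved 0 away from these spots.

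Arrays of opposite dye correlated negatively over all probes. Of the 30 probes highest on the arrays with ANIT in Cy5, 29 lay above the median on the arrays with ANIT in Cy3. This restates the observation for which the table was read as already turned to one treatment ratio with a dye difference left in it, and so is no separate support for that reading, which stays open. A dye ratio left unturned would make the mean of both orientations a property of the dyes. Fixed gene lists would then rarely stand apart if that property were unrelated to them. Of 21 list medians, 8 lay outside the central 95% of random lists matched on the difference between orientations, where 1.05 would be expected. There were 7 with the ribosomal list taken without S6 kinases, although some lists share genes. This cannot decide between the readings, because a dye property could itself differ between lists. Matching on the difference between orientations does not match brightness, which was not analysed.

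The difference between dye orientations varied widely between probes, and a candidate explanation is weak signal from genes that liver expresses little. Its median was -0.30 over 36 plasma protein and ribosomal genes and -1.54 over 45 markers of other cell types, 1.24 apart (two-sided permutation test with 100000 resamples, p = 6e-05), although some of those markers are also expressed in hepatocytes. The 11 ribosomal genes alone, without S6 kinases, had a median of -0.56, though Rpl17 had -2.17 and Rps3 -1.88. The S6 kinase genes left out, Rps6kb2, Rps6kb1 and Rps6ka4, had -1.30, -1.55 and -2.26. The 4 macrophage genes went against the pattern with -0.25. A treatment effect on the probes with a difference under -2 stays open, because their median ratio, -0.13 relative to the other probes, excludes nothing where weak signal would also draw ratios together (SD 0.080 against 0.402). Spot brightness, which would decide it, was not analysed here, and ratios near 0 for markers of other cell types may then say little about those cells.

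A hypothesis on the unstated direction is that the table holds ANIT over olive oil and that the ANIT pool shows an acute phase response. The median of 10 acute phase genes lay 0.487 above that of 7 negative acute phase genes, more than in 99.99% of 10000 random pairs of lists, or 99.62% of pairs matched on the difference between dye orientations. The turned sign would reverse this order, so the value is consistent with the direction used, given the background that acute phase genes rise in an injured liver. No value from a second pair of pools tests it.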
